A study of Mus musculus with 96 samples.

How the data were processed

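Total RNA of 96 mouse placentas (C57BL/6N) was extracted with TRIzol and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. The kit is not directional, so a gene and an overlapping gene on the other strand cannot be told apart. Dams had been injected with saline or with polyI:C at 20 mg/kg, and placentas of both sexes were taken at 3, 6, 12, 24, 48 or 144 h, per the labels. The labels also give 13 sequencing batches. Reads were trimmed with Trimmomatic 0.39, inspected with FastQC 0.11.5 and quantified with Salmon 0.8.2, per the submitters' processing notes.

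The deposited tables, 1 per library, list 133618 transcripts with GENCODE mouse names. Per the file headers they hold estimated counts (the reads Salmon assigns to each transcript) and TPM (transcript abundance scaled for length and depth), with an effective length. The release of the annotation and the genome build are not given in the sources used here. GENCODE M21 served only to give each gene a chromosome class, and held 99.82% of the gene identifiers. Library totals ran from 22.44 to 73.8 M estimated reads (median 51.4 M).

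Estimated counts were summed over the transcripts of each gene and rounded, which gave 52661 genes, 47778 of them with a read. No gene lacked a symbol, and 56 symbols were shared by several identifiers. The filterByExpr function of edgeR (minimum count 10, minimum total 15) kept 24987 genes and left out 27674. Counts were scaled by TMM. The quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 was fitted once to all 96 libraries with 1 coefficient for each of the 24 groups and sequencing batch as an additive block (36 coefficients, 60 residual degrees of freedom). All times therefore share the estimate of the spread. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Errors of log2 changes are standard errors. CPM are counts per M reads after TMM scaling.

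The comparisons were polyI:C minus saline at each time, averaged over the sexes and within each sex; the male minus the female effect at each time and averaged over times; a joint test of whether the effect differed among the 6 times; male minus female in saline; and saline at 144 h minus saline at 3 h. The effect was also compared between neighbouring times. The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined.

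For each time the named genes were the 8 with the largest rise and the 8 with the largest fall among those called, with a mean of at least 5 CPM in the higher treatment group and the same sign in all 8 within-batch pairs. Up to 4 called members with the smallest p were named for each list. For the sex difference, up to 5 genes in each direction were named, or those with the smallest p where none was called. For saline males against females, sex-linked genes and the 10 others with the smallest p were named, and for saline at 144 h against 3 h the 10 largest changes in each direction with no overlap between libraries. Gene models that carry only a clone, Gm or Rik name were passed over, and any named outside this rule is marked in the text.

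There were 29 pathway lists and 16 lists of cell type markers, with 854 genes, 809 of them measured. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and again with the correlation estimated from the data and with fry. Of 270 list tests over the 6 times, camera called 113, and 45 with an estimated correlation, 89 by fry and 111 without the batch block.

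Labels were checked against Xist and Y-linked genes, and pairs of libraries of a group for repeated data by a chi-square over genes with at least 20 reads. The male and female library of the same treatment, time and batch may come from the same dam, which the labels do not state. The correlation of such pairs in limma-voom was -0.00025. Libraries of the same batch and time had a median correlation of their deviations from group means of 0.02, against -0.01 for other batches. The labels state the batch, so the batch is in the design.

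The pipeline was tested on simulated data drawn from the means and sizes of these libraries. For the effect at 6 h, edgeR recovered 47 of 50 genes changed by 0.5 on the log2 scale and 50 of 50 changed by 1, with 6 calls among the unchanged of 24987 genes. For the sex difference at 24 h it recovered 40 and 47 of 50. With no gene changed, 0 genes were called at 12 h. Camera and fry each called 1 of 1 raised list of 25 genes and 0 of 44 random lists. The simulated genes varied independently and carried no batch effect, so lists whose genes vary together were not tested by it. No comparison at 144 h was simulated.

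Alternatives were DESeq2 1.42.0, its median-of-ratios factors in edgeR, no filter on low counts, length-scaled TPM counts, no batch block, a block for each batch and time, limma-voom with the correlation of the male and female pair, each time fitted alone, summed reads of the pair, and each library left out in turn. Plain limma-voom was added after the data were seen. It also served for leaving out libraries and for other splits of the samples. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 read the tables and drew the figures. No library was left out.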

Results

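RNA was sequenced from the placentas of C57BL/6N mice whose mothers had been injected with polyI:C or with saline. PolyI:C is a synthetic double-stranded RNA that imitates a viral infection, and its injection into pregnant dams is a model of maternal immune activation. Dams received 20 mg/kg of potassium polyI:C, or saline, at embryonic days 11.5 and 12.5, and placentas were collected 3, 6, 12, 24, 48 or 144 h after injection. Which of these injections the hours count from was not established here, so an effect at a given time may follow either or both. Each combination of treatment, fetal sex and time held 4 libraries, which gave 24 groups and 96 libraries. The libraries were sequenced in 13 batches, and each batch held 1 library of every treatment and sex for each time in it. The labels also give an isolation date, which all libraries of a batch share, so the batch block takes in the day of isolation. Library totals ran from 22.44 to 73.8 M estimated reads, with a median of 51.4 M. The labels do not tie placentas to dams. A male and a female placenta of the same treatment, time and batch may therefore share a mother, and the p-values measure the spread between these samples. That spread was estimated once over all 24 groups, so it is not the spread among the placentas of any 1 time.

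The fetal sex given by the labels was compared with reads of sex-linked genes. Xist, the RNA that silences an X chromosome in female cells, lay between 662 and 1450 counts per M reads (CPM) in the 48 libraries labelled female and between 51 and 209 CPM in the 48 labelled male. The summed Y-linked genes lay between 117 and 162 CPM in male libraries and between 2.49 and 4.44 CPM in female libraries. No library crossed over in either measure. Among 144 pairs of libraries of the same group, the lowest chi-square per degree of freedom was 3.3, so no pair differed by as little as sampling noise and every library was counted once. The median was 9.59. Saline female 24 h replicate 3 (52.9 to 65.4) and polyIC female 48 h replicate 1 (48 to 65.4) stood apart from their groups, with rRNA shares of 0.992% and 0.879% of reads.

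The main question of the design was how the placental transcriptome moved over the hours and days after maternal polyI:C. Averaged over both sexes, edgeR's quasi-likelihood test called 5927 of 24987 genes at 3 h, 4350 at 6 h, 175 at 12 h, 3028 at 24 h, 1466 at 48 h and 760 at 144 h. Most changes were small: the median absolute log2 change of the called genes was 0.17 at 3 h and 0.19 at 24 h. At least 2-fold changes were seen in 125 genes that rose and 41 that fell at 3 h, in 159 and 32 at 6 h, and in 30 and 41 at 24 h. The effect differed among the 6 times for 7020 genes. Between neighbouring times the effect was called different for 747 genes from 3 to 6 h, 2050 from 6 to 12 h, 471 from 12 to 24 h, 1210 from 24 to 48 h and 518 from 48 to 144 h.

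**Figure D1:**
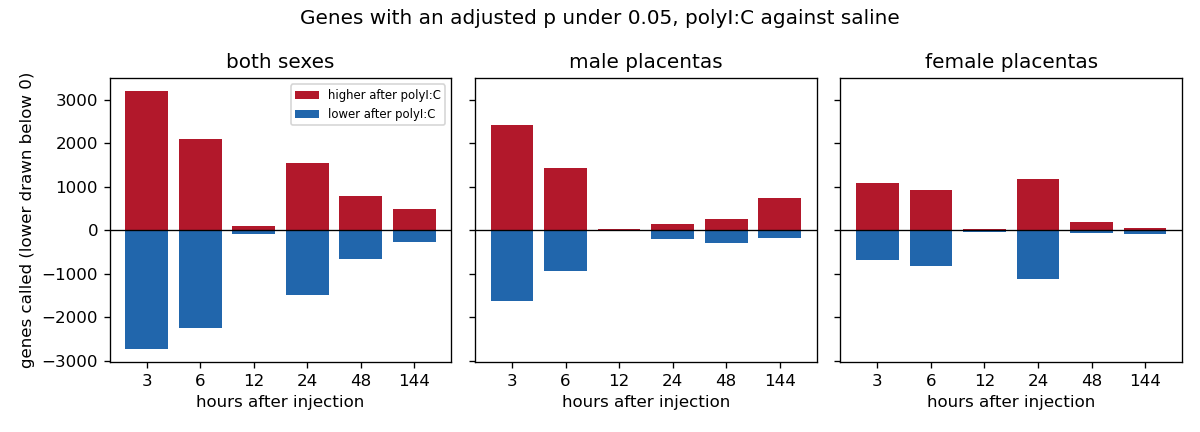
Genes with an adjusted p under 0.05 (edgeR) for polyI:C against saline, by hours after injection, for both sexes together and for each fetal sex. Bars above 0 count genes higher after polyI:C and bars below 0 count genes lower after polyI:C. The bars for both sexes reach 3193 genes higher and 2734 lower at 3 h, and 89 higher and 86 lower at 12 h.

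At 3 h after injection the placentas carried an interferon response. Cxcl10 (ENSMUSG00000034855.13), a chemokine induced by interferons, rose from 1.34 ± 0.23 CPM in saline to 36.2 ± 4.53 CPM after polyI:C (SD, n = 8 each), a log2 change of 4.75 ± 0.12 (SE) or 26.8-fold. Gbp5 (ENSMUSG00000105504.4), an interferon-inducible GTPase, rose from 2.22 ± 0.234 to 11.6 ± 1.41 CPM (log2 change 2.38 ± 0.10). The GTPase genes Mx1 and Mx2 rose by log2 changes of 2.21 ± 0.10 and 2.11 ± 0.06, Iigp1 by 2.11 ± 0.08, Ifit3b by 2.05 ± 0.09, Tgtp1 by 1.90 ± 0.12 and Ifit3 by 1.65 ± 0.08. Cd74 (ENSMUSG00000024610.14), the invariant chain of MHC class II, fell from 7.05 ± 0.738 to 3.5 ± 0.773 CPM (log2 change -1.03 ± 0.08). Each of these genes moved the same way in 8 of 8 batch-matched pairs of polyI:C and saline libraries, which the rule for named genes requires. Their edgeR adjusted p-values ran from 4.92e-43 for Cxcl10 to 2.43e-16 for Cd74. Mx1 and Mx2, Ifit3 and Ifit3b, and the Gbp and Irg GTPases belong to gene families whose members share sequence to differing degrees, so the split of reads among members is uncertain.

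The gene lists fixed before the data were examined gave the same picture by group. At 3 h, 50 of 52 measured type I interferon-stimulated genes rose and none fell (51 adjusted over the list alone; median log2 change 0.72; camera adjusted p = 1.97e-126). Among the list's members, Oas1b rose by 1.13 ± 0.04, Dtx3l by 1.24 ± 0.04 and Stat2 by 0.71 ± 0.02 on the log2 scale. Of 23 interferon-gamma-inducible GTPases and regulators, 21 rose and 1 fell (21 and 1 adjusted over the list alone), with Igtp at 1.57 ± 0.04 and Irgm2 at 1.23 ± 0.04. MHC class I presentation rose in 19 of 20 genes (20 adjusted over the list alone), by a median of 0.29, led by the peptide transporter subunit Tap1 at 0.68 ± 0.04 and by Tapbp at 0.32 ± 0.02. In contrast, 5 of 7 MHC class II genes fell (5 adjusted over the list alone; median -0.56), with H2-Aa at -1.09 ± 0.10 and H2-Eb1 at -0.91 ± 0.10. These 4 lists were also called with an estimated correlation.

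Inflammatory and leukocyte genes moved with the interferon genes at 3 h. Of 24 NF-kB feedback and target genes, 19 rose (20 adjusted over the list alone), among them the endothelial adhesion molecules Vcam1 (log2 change 0.77 ± 0.04) and Selp (1.63 ± 0.12). Of 23 chemokines, 11 rose (11 adjusted over the list alone), with Cxcl9 at 3.81 ± 0.22, Ccl5 at 2.31 ± 0.15 and Cxcl2 at 1.30 ± 0.12. Of 23 IL-6/STAT3 and acute-phase genes, 12 rose (13 adjusted over the list alone), with Stat3 at 0.51 ± 0.03 and its feedback inhibitor Socs3 at 0.65 ± 0.03. Il6 itself rose from a mean of 0.149 to 0.324 CPM (log2 change 1.14 ± 0.26, edgeR adjusted p = 0.000474). Markers of neutrophils rose in 7 of 16 genes and fell in 1 (7 and 1 adjusted over the list alone): S100a9 rose by 1.54 ± 0.11 and Retnlg by 2.68 ± 0.19. Markers of T and B lymphocytes fell in 5 of 16 genes (5 lower and 1 higher adjusted over the list alone), with the B cell genes Cd19 at -2.48 ± 0.25 and Cd79b at -1.01 ± 0.16, all at means under 1.1 CPM. With an estimated correlation the adjusted p of these 5 lists ran from 1.98e-05 for the NF-kB genes to 0.0123 for the neutrophil and lymphocyte markers.

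Genes of hypoxia, glucocorticoid response and protein folding also changed at 3 h, by smaller amounts. Of 21 hypoxia response genes, 13 rose (15 adjusted over the list alone), with the glycolytic regulator Pfkfb3 at 0.65 ± 0.07 and Ddit4 at 0.42 ± 0.05; camera's call was not held, with adjusted p = 0.0995 with an estimated correlation. Glucocorticoid-responsive genes rose in 9 of 20 (9 adjusted over the list alone; median 0.15; adjusted p = 0.0783 with an estimated correlation), with higher scores in 8 of 8 pairs and Per1 at 0.35 ± 0.04. Circadian clock genes rose in 4 of 18 (5 adjusted over the list alone; median 0.09; adjusted p = 0.0783 with an estimated correlation). Of 19 unfolded protein response genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone), with the chaperone partners Dnajb9 at -0.30 ± 0.03 and Manf at -0.31 ± 0.04 (adjusted p = 0.417 with an estimated correlation). The 13 mitochondrially encoded mRNAs fell in 9 cases (9 adjusted over the list alone; median -0.15), with mt-Cytb at -0.21 ± 0.05 (adjusted p = 0.438 with an estimated correlation). Trophoblast giant cell genes went both ways, 2 higher and 6 lower of 21 (4 and 7 adjusted over the list alone; camera adjusted p = 0.177). Cts6 (ENSMUSG00000021441.4), a placental cathepsin, fell from 13 ± 3.42 to 7.01 ± 0.958 CPM, and the lactogen gene Prl3b1 fell by 0.26 on the log2 scale. Among genes that met the naming rule (at least 5 CPM and the same sign in all 8 pairs), others with the largest falls were Susd3 (-0.73 ± 0.06), Cabp7 (-0.63 ± 0.08), Ankrd35 (-0.62 ± 0.05), Fndc5 (-0.62 ± 0.06), Heyl (-0.51 ± 0.06) and 1 of 2 gene models that share the symbol Zc3h11a (-0.54 ± 0.12).

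At 6 h the type I interferon-stimulated genes stood higher still. All 52 type I interferon-stimulated genes rose (52 adjusted over the list alone; median log2 change 1.21; camera adjusted p = 6.99e-204), with Parp9 at 1.48 ± 0.03, the RNA sensor Ifih1 at 1.40 ± 0.04 and Ddx58 at 1.11 ± 0.03. Relative to 3 h, the effect was higher for 34 of the 52 and lower for 5. Among 23 interferon-gamma-inducible genes it was higher for 4 and lower for 6 (median change of the effect -0.11). Among 23 chemokines it was lower for 3. Cxcl10 had come down to 6.12 ± 0.957 CPM against 1.29 ± 0.229 in saline (log2 change 2.24 ± 0.13), and Iigp1 stood at 21.6 ± 2.81 against 4.68 ± 0.727 CPM (2.20 ± 0.08). Igfbp1, a growth factor binding protein that decidua secretes, rose by 2.15 ± 0.19, Gbp2 by 2.01 ± 0.07, Ifit1 by 1.95 ± 0.08, Zbp1 by 1.93 ± 0.08, Tor3a by 1.87 ± 0.05 and Rnf213 by 1.86 ± 0.05. Cd74 was lower, at 3.01 ± 0.314 against 6.65 ± 0.778 CPM (-1.14 ± 0.09), and Fam135b fell by 0.70 on the log2 scale, from 8.62 ± 1.11 to 5.3 ± 0.919 CPM. The genes named for the largest changes moved the same way in 8 of 8 pairs, which the rule for named genes requires.

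By group at 6 h, 21 of 23 interferon-gamma-inducible genes rose and 1 fell (22 and 1 adjusted over the list alone), and 19 of 20 MHC class I genes rose (20 adjusted over the list alone), with Tap1 at 1.27 ± 0.04. The dsRNA receptor Tlr3 rose by 1.67 ± 0.05 and its partner list of pattern recognition receptors had 8 of 16 higher and 1 lower (9 and 1 adjusted over the list alone). MHC class II genes fell in 5 of 7 (6 adjusted over the list alone; median -0.53). Neutrophil markers rose in 8 of 16 (8 adjusted over the list alone), and T and B lymphocyte markers fell in 5 of 16 and rose in 1 (5 and 1 adjusted over the list alone), with Cd19 at -2.43 ± 0.25. At 6 h 6 NF-kB genes were called higher and 1 lower (camera adjusted p = 0.15 with an estimated correlation), against 19 higher at 3 h. The effect itself fell from 3 to 6 h for 9 of the 24. Hypoxia response genes rose in 16 of 21 and fell in 1 (17 and 1 adjusted over the list alone; median 0.20), with Egln1 at 0.30 ± 0.03, Bnip3 at 0.38 ± 0.04 and Pdk1 at 0.30 ± 0.03. Unfolded protein response genes fell in 11 of 19 (13 lower and 1 higher adjusted over the list alone), with Creld2 at -0.31 ± 0.05 (adjusted p = 0.405 with an estimated correlation). Glucocorticoid-responsive genes rose in 7 of 20 and fell in 2 (7 and 2 adjusted over the list alone; median 0.10; adjusted p = 0.342 with an estimated correlation). Circadian clock genes rose in 8 of 18 and fell in 1 (9 and 1 adjusted over the list alone; median 0.13; adjusted p = 0.0834 with an estimated correlation). When the 16 libraries of 6 h were fitted alone, 2638 genes were called in place of 4350.

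At 12 h after injection little was called. The type I interferon-stimulated genes were still higher in 24 of 52 (35 adjusted over the list alone), but by a median of 0.19, and the effect had fallen from 6 to 12 h for 48 of the 52. Of all genes, 12 rose at least 2-fold. Among those that met the naming rule (at least 5 CPM and the same sign in all 8 pairs), the largest rises were of S100a9, a calcium-binding protein abundant in neutrophils, from 1.96 ± 0.122 to 5.45 ± 0.851 CPM (log2 change 1.47 ± 0.12), of Zbp1 from 4.02 ± 0.434 to 6.32 ± 0.726 CPM (0.65 ± 0.09), and of Tor3a (0.56 ± 0.05), Oas1g (0.46 ± 0.05), Oas1a (0.44 ± 0.04), Gbp3 (0.40 ± 0.06), Tap1 (0.39 ± 0.04) and Lgals3bp (0.38 ± 0.04). Cd74 was lower at 2.89 ± 0.496 against 5.27 ± 0.562 CPM (-0.88 ± 0.09) and Cts6 at 22.1 ± 7.57 against 32.9 ± 6.7 CPM (-0.60 ± 0.12). Rab30 (-0.41 ± 0.06), Kbtbd11 (-0.40 ± 0.06), Ptgdr2 (-0.37 ± 0.09), Pdk4 (-0.36 ± 0.07), Flt3 (-0.34 ± 0.08) and Rab27a (-0.33 ± 0.07) also fell. All of these moved the same way in 8 of 8 pairs, which the rule for named genes requires. MHC class I genes rose in 4 of 20 (11 adjusted over the list alone), MHC class II genes fell in 3 of 7 (5 adjusted over the list alone; median -0.47) and neutrophil markers rose in 5 of 16 (5 adjusted over the list alone). Glucocorticoid-responsive genes fell in 3 of 20 (6 adjusted over the list alone), with Pdk4, Per1 (-0.17 ± 0.04) and Ddit4 (-0.20 ± 0.05), at adjusted p = 0.217 with an estimated correlation. With limma-voom the count was 180 with all libraries, 113 without saline female 12 h replicate 3 and 114 without polyIC male 12 h replicate 3.

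At 24 h more genes were called than at 12 h, and cell cycle genes were lower. All 22 measured G2/M genes fell (22 adjusted over the list alone; median log2 change -0.33; camera adjusted p = 2.05e-39), among them cyclin Ccnb2 (-0.41 ± 0.04), Birc5 (-0.44 ± 0.04), Cenpf (-0.41 ± 0.04) and Nusap1 (-0.35 ± 0.04). The effect on these genes had fallen from 12 to 24 h for 18 of the 22 and rose again from 24 to 48 h for all 22. The G2/M score was lower after polyI:C in 8 of 8 batch-matched pairs, by between -0.45 and -0.25. DNA replication and S phase genes fell in 7 of 22 (13 adjusted over the list alone), with Ccne1 at -0.27 ± 0.06 (adjusted p = 0.195 with an estimated correlation). Definitive erythroid genes fell in 4 of 13 (4 lower and 1 higher adjusted over the list alone), with Epb42 at -0.68 ± 0.11 and Slc4a1 at -0.56 ± 0.10 (adjusted p = 0.322 with an estimated correlation). The embryonic globin Hbb-bh1 (-0.74 ± 0.12) and the blood group protein gene Kel (-0.86 ± 0.11) were lower too.

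Leukocyte and metabolic genes also differed at 24 h. MHC class II genes fell in 6 of 7 (6 adjusted over the list alone; median -0.77), with H2-Aa at -1.43 ± 0.11 and Cd74 at 2.61 ± 0.354 against 5.8 ± 0.735 CPM (-1.15 ± 0.09), and T and B lymphocyte markers fell in 4 of 16 (4 adjusted over the list alone), with Cd19 at -1.88 ± 0.22. S100a9 stood at 6.46 ± 0.339 against 2.16 ± 0.22 CPM (1.58 ± 0.11), within neutrophil markers that rose in 6 of 16 and fell in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.0551 with an estimated correlation). Serpina3n rose from 3.82 ± 0.443 to 6.8 ± 0.707 CPM (0.84 ± 0.18), and the placental prolactin-family hormones Prl8a6 and Prl3a1 rose by 0.76 ± 0.08 and 0.65 ± 0.11. Aadac fell from 6.36 ± 0.509 to 3.46 ± 0.509 CPM (-0.88 ± 0.09), and Apoh (-0.67 ± 0.10), Cxcl14 (-0.62 ± 0.14) and Slfn4 (-0.62 ± 0.13) fell with it. Nutrient transporters rose in 12 of 24 and fell in 1 (13 and 1 adjusted over the list alone), with the fatty acid binding protein Fabp3 at 0.29 ± 0.04 and the amino acid transporter Slc7a5 at 0.34 ± 0.06 (adjusted p = 0.0754 with an estimated correlation). Of 22 cholesterol biosynthesis genes, 11 fell (18 adjusted over the list alone), with Insig1 at -0.35 ± 0.05 and Fdps at -0.31 ± 0.05 (adjusted p = 0.262 with an estimated correlation). In the tryptophan and serotonin list, which camera did not call (adjusted p = 0.0672), 7 of 16 genes fell and 2 rose (8 and 3 adjusted over the list alone): the kynurenine pathway enzymes Haao and Kmo fell by 0.61 and 0.69 on the log2 scale, and the monoamine oxidase gene Maoa rose by 0.32 ± 0.05. MHC class I genes rose in 15 of 20 (17 adjusted over the list alone), and type I interferon-stimulated genes rose in 15 of 52 and fell in 2 (20 and 2 adjusted over the list alone), with a median of 0.07 and adjusted p = 0.403 with an estimated correlation.

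At 48 h the placentas showed myeloid genes above saline. Of 16 neutrophil markers, 11 rose (12 adjusted over the list alone; median log2 change 0.83; camera adjusted p = 8.86e-23), with S100a9 at 5.66 ± 1.54 against 2.56 ± 1.14 CPM (1.19 ± 0.12), Ngp at 3.28 ± 0.41 and Retnlg at 1.89 ± 0.24. Macrophage and monocyte markers rose in 11 of 19 (14 higher and 1 lower adjusted over the list alone; median 0.27), with Adgre1 at 0.64 ± 0.08, Clec4n at 1.27 ± 0.16, Marco at 1.17 ± 0.15 and Itgam at 0.69 ± 0.09, and the effect on 10 of them was higher than at 24 h. Complement genes rose in 5 of 17 (6 adjusted over the list alone), with C1qb at 0.64 ± 0.07 and C5ar1 at 0.92 ± 0.10, and chemokines rose in 9 of 23 (11 adjusted over the list alone), with Ccl12 at 1.16 ± 0.19. Ifi27l2a rose from 3.06 ± 0.649 to 5.78 ± 2.22 CPM (0.90 ± 0.11), with type I interferon-stimulated genes higher in 19 of 52 (34 adjusted over the list alone; median 0.15). Sprr2a2 (0.83 ± 0.17), Sprr2a3 (0.74 ± 0.20), Cxcl10 (0.79 ± 0.12), Ms4a6d (0.75 ± 0.10) and Lyz2 (0.65 ± 0.09) rose as well. The Sprr2a copies share sequence, so their reads cannot be assigned with certainty. Haemoglobin genes took a smaller share of reads after polyI:C in 8 of 8 pairs at 48 h, with means of 1.25% against 1.62%, a comparison chosen after the results were seen.

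The genes that fell at 48 h included most enzymes of cholesterol synthesis. Cts6 fell from 414 ± 110 to 240 ± 65.1 CPM (-0.80 ± 0.11), Saa3 from 20.8 ± 2.41 to 13.3 ± 2.98 CPM (-0.66 ± 0.15), and Apoh (-0.62 ± 0.10), Ahsg (-0.52 ± 0.07), Lrrn4 (-0.51 ± 0.06), Sycn (-0.50 ± 0.08), Slco1b2 (-0.49 ± 0.09) and Hspa12a (-0.48 ± 0.08) fell too. They fell in 8 of 8 pairs, which the rule for named genes requires. Of 22 cholesterol biosynthesis genes, 17 fell (17 adjusted over the list alone; median -0.25; camera adjusted p = 3.12e-23), with Dhcr7 at -0.40 ± 0.05, Fdft1 at -0.27 ± 0.04 and Cyp51 at -0.31 ± 0.05. Visceral endoderm and yolk sac markers fell in 4 of 16 (6 adjusted over the list alone), with Amn at -0.24 ± 0.07 (adjusted p = 0.322 with an estimated correlation). MHC class II genes fell in 4 of 7 (4 adjusted over the list alone; median -0.30), while none of the T and B lymphocyte markers fell and 1 rose.

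At 144 h 495 genes were higher and 265 lower. Among the higher genes 187 were also higher at 3 h (63.3 if independent). Among the lower genes 38 were also lower at 3 h (29 if independent), and 77 genes were called in opposite directions at 3 and 144 h. Zbtb16, a transcription factor gene induced by glucocorticoids, rose from 10.6 ± 1.78 to 18.5 ± 2.74 CPM (log2 change 0.81 ± 0.09, against 0.45 ± 0.09 at 3 h), and Fam107a from 3.85 ± 0.748 to 5.76 ± 0.927 CPM (0.58 ± 0.09). Ghrh, which encodes growth hormone-releasing hormone, fell from 110 ± 22.9 to 74.6 ± 17.3 CPM (-0.58 ± 0.06, against -0.38 ± 0.06 at 3 h), and Rnf222 from 5.04 ± 0.603 to 3.44 ± 0.646 CPM (-0.57 ± 0.10). Hspa1a (0.57 ± 0.10) and its near-identical copy Hspa1b (0.45 ± 0.08), Arg2 (0.44 ± 0.12), Dio2 (0.44 ± 0.10), Hmcn1 (0.39 ± 0.07) and Ly75 (0.38 ± 0.06) rose. Klk4 (-0.46 ± 0.09), Adgrl1 (-0.25 ± 0.04), Kank4 (-0.23 ± 0.06), Upp1 (-0.22 ± 0.05), Timp3 (-0.22 ± 0.05) and Zfp810 (-0.20 ± 0.03) fell. All 16 moved the same way in 8 of 8 pairs, which the rule for named genes requires. Glucocorticoid-responsive genes rose in 9 of 20 (14 adjusted over the list alone; median 0.14), with Fkbp5 at 0.43 ± 0.06, heat shock genes in 5 of 13 (9 adjusted over the list alone), and circadian clock genes in 4 of 18 (6 adjusted over the list alone), with Per2 at 0.34 ± 0.05 (list median 0.07). These lists had adjusted p-values of 0.00781, 0.0269 and 0.0269 with an estimated correlation. The glucocorticoid-responsive and clock lists had also risen at 3 and 6 h, with medians of 0.15 and 0.10 and of 0.09 and 0.13. Those 4 calls were not held, at adjusted p = 0.0783, 0.342, 0.0783 and 0.0834 with an estimated correlation. At 6 h, 7 of 20 and 8 of 18 of their genes were higher and 2 and 1 lower. Syncytiotrophoblast genes fell in 3 of 18 (7 adjusted over the list alone), with the fusogen Synb at -0.52 ± 0.10 (adjusted p = 0.774 with an estimated correlation). Interferon-stimulated genes were higher in 8 of 52 (11 adjusted over the list alone; median 0.05; adjusted p = 0.558 with an estimated correlation). The count at 144 h depended on the fit: with the 16 libraries of 144 h fitted alone, 14 genes were called in place of 760, and without a filter on low counts 469 were. With limma-voom, 784 genes were called with all libraries and 1187 without saline male 144 h replicate 1, and leaving out saline female 144 h replicate 1, saline male 144 h replicate 2 or polyIC female 144 h replicate 2 gave 368, 403 and 432.

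**Figure D2:**
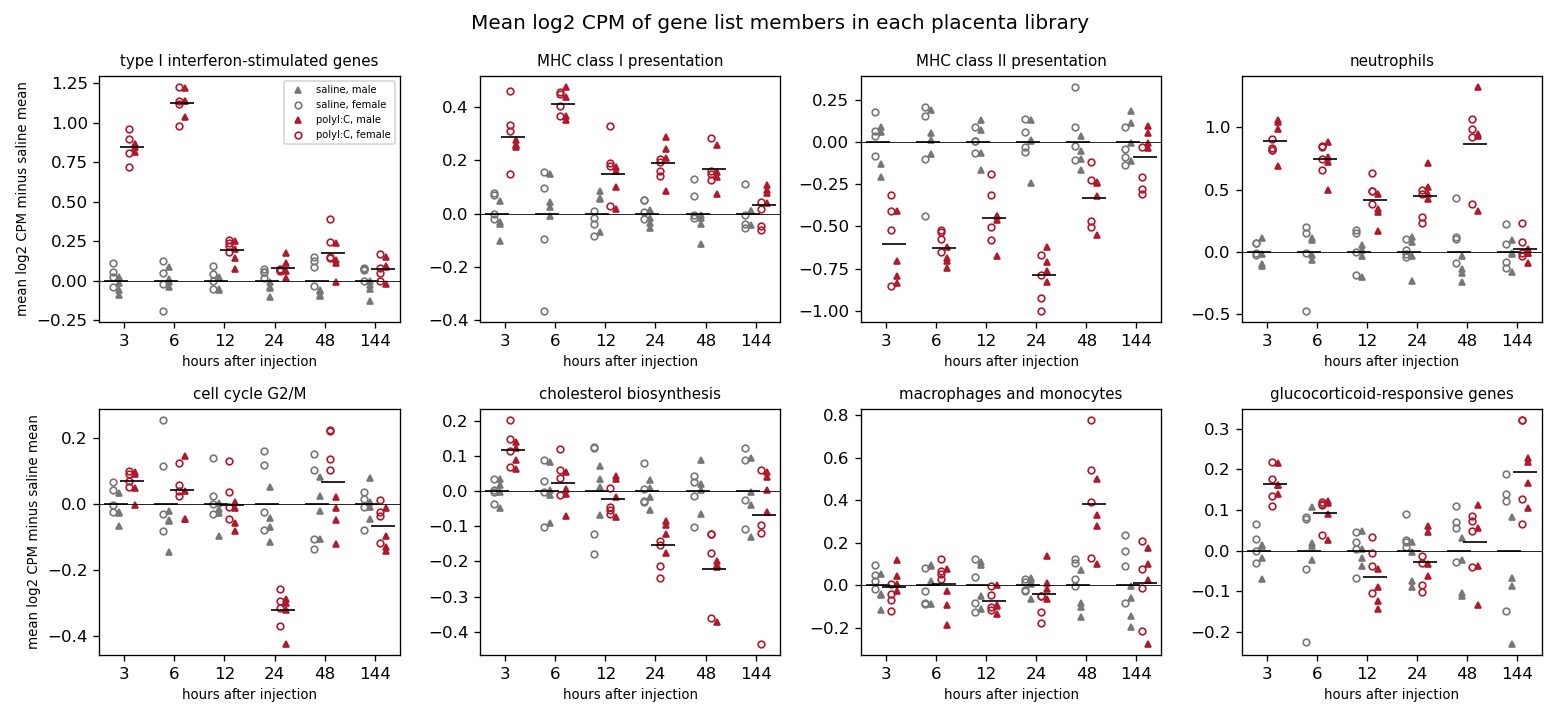
Mean log2 CPM of the members of 8 gene lists in each of the 96 libraries, minus the mean of the 8 saline libraries of the same time (y axis, log2 units), by hours after injection (x axis). Grey symbols are saline and red symbols polyI:C, triangles are male and circles female placentas, and short lines are means. All 8 polyI:C libraries lie below 0 in the G2/M panel at 24 h, and the within-pair differences there run from -0.45 to -0.25.

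The design also asked whether male and female placentas responded differently. In male placentas alone edgeR called 4053, 2355, 53, 347, 545 and 914 genes at 3, 6, 12, 24, 48 and 144 h, and in female placentas 1750, 1752, 62, 2295, 263 and 138. These counts do not test a difference between the sexes. Among genes called in males at 3 h, 96.6% had the same sign in females, and among those called in females 99.1% had the same sign in males. At 24 h these shares were 95.7% and 93.6%, and at 144 h they were 62.7% and 75.4%. The genes called in both sexes, 1387 at 3 h, 998 at 6 h, 28 at 12 h, 270 at 24 h, 130 at 48 h and 25 at 144 h, all moved the same way. Independent lists of these sizes would share 283.9 genes at 3 h and 5 at 144 h. Fitted alone, the 16 libraries of 144 h gave 0 calls in males and 2 in females by edgeR, against 4122 and 2608 genes at an unadjusted p under 0.05 with all times and 1350 and 229 calls by DESeq2 with all times. The counts within a sex also moved with single libraries. With limma-voom the male count at 144 h was 912 with all libraries, 46 without saline male 144 h replicate 2 and 1683 without saline male 144 h replicate 1. The female count was 159, 35 without saline female 144 h replicate 4 and 410 without saline female 144 h replicate 2. The lowest male counts at 3, 6, 12, 24 and 48 h were 2731, 1528, 28, 136 and 201 against 4131, 2356, 47, 336 and 442, without polyIC male 3 h replicate 4, polyIC male 6 h replicate 3, polyIC male 12 h replicate 3, polyIC male 24 h replicate 3 and polyIC male 48 h replicate 4. The lowest female counts at 3, 6, 12, 24 and 48 h were 976, 978, 36, 1490 and 75 against 1791, 1772, 51, 2496 and 250, without polyIC female 3 h replicate 1, saline female 6 h replicate 2, polyIC female 12 h replicate 2, saline female 24 h replicate 3 and polyIC female 48 h replicate 3.

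The difference between the sexes was tested as the male minus the female effect. At 3, 6 and 24 h edgeR called 0 genes, with 957, 1408 and 1374 genes at an unadjusted p under 0.05; DESeq2 called 3, 7 and 6 and limma-voom 0 at each. The smallest p-values there belonged to Plin5 (log2 difference -1.10 ± 0.26), Cckbr (-2.85 ± 0.70) and Tarsl2 (0.77 ± 0.16), with edgeR adjusted p-values of 1, 0.857 and 0.21. At 12 h 2 genes were called. Grip2, a scaffold protein gene, had a difference of 2.43 ± 0.42, and the clone-named RP23-378I13.5, named after the values were seen because the count is small, one of 1.03. DESeq2 called 14 genes and limma-voom 1, and edgeR called 0 when 12 h was fitted alone. Grip2 stood at 52.2 and 60 CPM in 2 of the 4 male polyI:C libraries and at 4.59 and 6.1 CPM in the other 2, against 4.4 to 6.45 CPM elsewhere at 12 h. RP23-378I13.5 lay between 10.2 and 40.3 CPM in female polyI:C libraries and between 46.3 and 62.2 CPM in the other 12 libraries. At 48 h DESeq2 called 11 genes and limma-voom 0. The 1 gene called by edgeR, RP23-215D22.2 (also named after the values were seen), had no reads in the male polyI:C libraries, and its 4 male saline libraries held 0.094, 0.342, 0 and 15.4 CPM, so that 1 library carried the signal.

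At 144 h 135 genes differed between the sexes in their effect, 123 with the higher effect in males and 12 with the lower. Meltf, a cell-surface transferrin homolog, rose in males from 17.3 ± 2.21 to 23.6 ± 0.789 CPM (log2 change 0.45 ± 0.10) and had 24.1 ± 2.88 in saline and 19.4 ± 3.77 CPM after polyI:C in females (-0.29 ± 0.10; SD, n = 4 each), a difference of 0.74 ± 0.14. The lysosomal enzymes Lgmn and Neu1 had differences of 0.40 ± 0.08 and 0.26 ± 0.05, the serine racemase gene Srr 0.28 ± 0.05 and the water channel gene Aqp3 0.40 ± 0.08. The lower effects in males were of Krt6a (-0.95 ± 0.19), Cyp2c68 (-3.67 ± 0.74, at means under 0.2 CPM), Mal (-0.99 ± 0.20), Tmem44 (-0.60 ± 0.12) and the platelet chemokine Ppbp (-1.36 ± 0.31). Visceral endoderm and yolk sac markers were the list with the smallest p, with 3 of 16 higher in males (14 adjusted over the list alone; median 0.55; camera adjusted p = 2.63e-17; adjusted p = 0.211 with an estimated correlation). No gene was called when 144 h was fitted alone by edgeR, against 2929 at an unadjusted p under 0.05 with all times, 505 calls by DESeq2 and 125 by limma-voom, and limma-voom called 0 without saline male 144 h replicate 2 and 840 without polyIC female 144 h replicate 2. Averaged over the 6 times, 2 genes differed: Ddit4, a stress-induced inhibitor of growth signalling, by 0.20 ± 0.04 (edgeR adjusted p = 0.038) and the low-count Gm25315, named after the values were seen, by -3.61 ± 0.71. Without the batch block, and with a block for each batch and time, edgeR called 0 genes (1327 at an unadjusted p under 0.05 with the batch block), limma-voom called 0 and DESeq2 called 22, 63.6% of them higher against 50% by edgeR.

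Sex differences in the absence of treatment were taken over the 48 saline libraries, which held 24 of each sex. Of 34 tested Y-linked genes 24 were called, 23 of them higher in males, with Ddx3y at 70 ± 6.82 CPM in males against 0.164 ± 0.0554 in females and Eif2s3y at 30.1 ± 5.59 against 0.106 ± 0.0457 (SD, n = 24 each). On the X chromosome 152 of 826 genes were called, 103 higher in females and 49 higher in males. Xist was the most different of them (133 ± 45.4 CPM in males, 1170 ± 220 in females), and genes known to escape X inactivation were higher in females: Eif2s3x by a male minus female log2 difference of -0.50 ± 0.01, Kdm5c by -0.32 ± 0.02, Kdm6a by -0.23 ± 0.01 and Ddx3x by -0.09 ± 0.02. Ogt (-0.59 ± 0.02) and Taf1 (-0.49 ± 0.01) were also higher in females. On the autosomes 2902 of 24059 genes were called, with a median absolute difference of 0.10. Those with the smallest p-values included Mgea5 (-0.18 ± 0.01), which encodes the enzyme that removes the sugar that the Ogt product adds, Rgs5 (0.36 ± 0.03), Slc38a6 (0.31 ± 0.03), Ppp2r2c (0.29 ± 0.02) and the germline gene Asz1 (1.09 ± 0.09). By time, the saline sexes differed in 76, 107, 168, 108, 130 and 1453 genes at 3, 6, 12, 24, 48 and 144 h. Each of these counts rests on 4 libraries of each sex and on the spread shared by all times. No alternative fit and no left-out library was run for them, and other counts at 144 h depended on the fit.

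The saline placentas of 3 and 144 h compare early and late placentas without treatment. They differed in 17195 of 24987 genes, 8277 higher at 144 h and 8918 higher at 3 h. Only batch 1851 held libraries of both times, so unlike the treatment effects this comparison was not balanced over batches. It rested mostly on the additive batch block. Embryonic globins fell the most: Hbb-y from 5190 ± 713 to 0.622 ± 0.241 CPM (log2 change -13.29 ± 0.22), Hbb-bh1 by -12.82 ± 0.36 and Hba-x by -11.03 ± 0.20. Doxl2 rose from 3.83 ± 1.09 to 2420 ± 473 CPM (9.29 ± 0.12), the hormone gene Prl3a1 by 8.58 ± 0.15, the cathepsin gene Cts6 by 7.34 ± 0.17, the sodium channel gene Scn9a by 7.61 ± 0.19 and Tph1, which encodes tryptophan hydroxylase, by 7.10 ± 0.15. Ces3a went from 0 reads in the 8 libraries of 3 h to 2102 reads at 144 h. Slc51b, Ceacam-ps1, Krt6a and Serpina4-ps1 were among the other largest rises, and Ceacam9, Dio3, Aadac, C1ql2, Cyp2c68, Col2a1 and Tac2 among the other largest falls (log2 changes from -7.93 to -6.15). All 22 G2/M genes and all 22 DNA replication genes were lower at 144 h (22 and 22 adjusted over the lists alone), with medians of -3.60 and -1.87 and adjusted p-values of 0.0161 and 0.0127 with an estimated correlation. All 42 ribosomal protein genes were lower as well (42 adjusted over the list alone; median -0.76; adjusted p = 0.179 with an estimated correlation), as were 14 of 16 natural killer cell markers, with 1 higher (14 and 1 adjusted over the list alone; median -3.07; adjusted p = 0.315 with an estimated correlation). Interferon-gamma-inducible genes were higher in 19 of 23 and lower in 2 (20 and 2 adjusted over the list alone; median 0.96; adjusted p = 0.172 with an estimated correlation). Uterine smooth muscle markers were higher in 8 of 9 genes and lower in 1 (8 and 1 adjusted over the list alone). Their median was 2.13, with camera adjusted p = 0.172 with an estimated correlation. Whether the share of maternal or other tissue in the samples differed between the times was not tested, so these changes cannot all be read as maturation. Time and embryonic age cannot be told apart in this comparison, since every placenta of a later time was also older.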

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

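In this part the use of limma-voom for leaving out libraries and for other splits of the samples, the test of a sex difference among the saline libraries of 144 h, and the size of the differences at 144 h with a library left out, were chosen after the results were seen.

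Of 124 groups of 4 or 8 values examined for a sample far from the others, 5 held one. Chance alone gives about 1 in 20 groups. The depth of polyIC female 12 h replicate 1 was 73.8 M reads, with the nearest of its group at 42.1 M. Gbp5 in saline female 3 h replicate 4 stood at 2.72 CPM (nearest 2.32), Cd74 in saline male 24 h replicate 4 at 4.1 CPM (nearest 5.65), S100a9 in saline female 48 h replicate 2 at 5.27 CPM (nearest 2.56) and Hbb-bh1 in saline female 3 h replicate 3 at 287 CPM (nearest 225).

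The effect of polyI:C differed among the 6 times for 7020 genes by edgeR. With limma-voom 7208 genes were called, 1 of 50 splits gave as many (the real one), and the highest other split gave 2210. The splits moved treatment labels across batches at random, so they need not keep the batch balance of the real split. They do not exclude chance by themselves.

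The male and female effects differed for 2 genes at 12 h, 1 at 48 h, 135 at 144 h and 2 in the mean over times by edgeR. Chance cannot be excluded for the counts at 12 and 144 h. With limma-voom, 24 of 100 splits at 12 h gave at least the real count of 1 (highest other 301), and 28 of 100 at 144 h gave at least the 121 autosomal genes called (highest other 2404). For the mean over times (50 of 50 splits, highest other 63) and at 3, 6, 24 and 48 h (100 of 100 splits, highest others 766, 638, 436 and 889) limma-voom called 0 genes in the real split, so every split gave as many by construction, and these splits say nothing about the edgeR counts of 1 and 2. The splits swapped the sex labels within pairs of the same treatment, time and batch. Where the swapped pairs were mostly of a single treatment, the test took in the sex difference itself, called for 2902 autosomal genes in saline. High counts of other splits can come from that, so the splits do not decide whether the counts at 12 and 144 h are chance. At 12 h Grip2 differed by 2.43, carried by 2 of 4 male polyI:C libraries. In the mean over times Ddit4 differed by 0.20.

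The sex difference at 144 h was weighed, with the named genes Meltf (0.74), Lgmn (0.40), Srr (0.28), Neu1 (0.26), Aqp3 (0.40), Krt6a (-0.95), Cyp2c68 (-3.67), Mal (-0.99), Tmem44 (-0.60) and Ppbp (-1.36). For one library that stands apart, the lowest limma-voom count was 0 in place of 125, without saline male 144 h replicate 2, but it was also 1 without polyIC female 144 h replicate 3, 3 without polyIC male 144 h replicate 3 and 5 without saline female 144 h replicate 4, so no single library was singled out and the explanation stays open. The median absolute difference of the 135 genes was 0.31 (median SE 0.08) with all libraries and 0.27, 0.27, 0.29 and 0.28 without these 4 (median SE 0.08 each). Without other libraries it lay between 0.30 and 0.38, the highest without polyIC female 144 h replicate 2. The 135 genes were picked by their calls with all libraries, so these medians do not decide why calls were lost. Yolk sac tissue in some libraries cannot be told apart, since with the yolk sac score as covariate the median absolute difference of the called genes was 50.8% of that without it (0.16 against 0.31). A sex difference among the saline libraries of 144 h cannot be told apart either: the larger difference lay in saline for 59.8% of the called autosomal genes, with medians of 0.17 in saline and 0.14 after polyI:C. EdgeR's test of the male minus the female effect called 135 genes. Whether these reflect a different response of male and female placentas or 1 of the explanations above stays open.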

How the results depend on the processing

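Plain limma-voom, used also for leaving out libraries, was chosen after the data were seen. The counts at 3, 24 and 48 h averaged over the sexes, the joint test, the saline sex difference and saline 144 h minus 3 h stayed within 1.5 times of their value under every alternative run for them. The cause of the other shifts was not tested. Each time fitted alone gave 2638 genes at 6 h (60.1% higher against 48.3%) and 14 at 144 h for both sexes, 1108 at 6 h, 685 at 24 h and 0 at 144 h in males (edgeR; 4122 at an unadjusted p under 0.05 with all times, 1350 calls by DESeq2), 728 at 6 h, 94 at 12 h, 3567 at 24 h and 2 at 144 h in females, and for the sex difference 0 at 12 h, 1 at 24 h, 0 at 48 h and 0 at 144 h. No filter on low counts gave 469 at 144 h. Length-scaled TPM counts gave 174 in males at 24 h, 159 and 61 in females at 48 and 144 h, and 1 and 87 for the sex difference at 12 and 144 h. DESeq2 gave 99 and 229 in females at 12 and 144 h, and 3, 7, 14, 6, 11 and 505 for the sex difference at 3, 6, 12, 24, 48 and 144 h, with 22 for its mean over times (63.6% higher against 50%). For the sex difference, no replicate block gave 1 at 12 h, 0 at 48 h and 0 for the mean over times, and the replicate block per batch and time gave 0 for the mean over times; neither setting moved any other count of genes by over 1.5 times. Limma-voom, with or without the correlation of a litter pair, gave 1, 0 and 0 for the same 3 counts. With an estimated correlation 37 of 87 pathway list calls and 8 of 26 cell type list calls were made. Gbe1 at 3 h turned from 0.15 to -0.03 with length-scaled TPM counts.

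Leaving out each library in turn (limma-voom) gave, at 3, 6, 12, 24, 48 and 144 h, ranges of 4902 to 6310, 3399 to 4763, 113 to 185, 2493 to 3122, 1035 to 1357 and 368 to 1187 for both sexes; 2731 to 3874, 1528 to 2067, 28 to 43, 136 to 264, 201 to 440 and 46 to 1683 in males; 976 to 2096, 978 to 2361, 36 to 56, 1490 to 2376, 75 to 232 and 35 to 410 in females; and 0 to 0, 0 to 0, 0 to 3, 0 to 0, 0 to 1 and 0 to 840 for the sex difference, with 0 to 4 for its mean over times. The other ranges were 2654 to 3207 for the saline sex difference, 16715 to 17219 for saline 144 h minus 3 h and 6803 to 7784 for the joint test. Of 7313 values of named genes under the alternatives, 7002 kept direction and call, 310 kept direction without the call and 1 reversed; of 15040 with a library left out, 14018 and 1022 did and 0 reversed. The lowest depth was 22.44 M reads, and genes near 1 CPM rest on few reads there.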

Other observations

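In this part the tests made with limma-voom, and the test of fewer leukocytes of every kind, were chosen after the results were seen.

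For the polyI:C effect averaged over sexes, with limma-voom 1 of 35 splits, the real one, gave as many genes at each time. That is the smallest share that 35 splits can give. The splits moved treatment labels across batches, and those that keep every batch balanced are too few to exclude chance by themselves. The real counts at 3, 6, 12, 24, 48 and 144 h were 5956, 4308, 180, 3180, 1369 and 784, and the highest other splits 3175, 2173, 46, 1333, 338 and 447. At 144 h the count was 368 without saline female 144 h replicate 1, 403 without saline male 144 h replicate 2 and 432 without polyIC female 144 h replicate 2, each below the highest other split, and edgeR called 14 genes when 144 h was fitted alone. Other splits gave fewer genes in males too (4131, 2356, 47, 336, 442 and 912, with highest others of 1148, 617, 9, 154, 49 and 752; at 144 h the male count of 912 was 46 without saline male 144 h replicate 2, and edgeR called 0 genes in males, 4122 at an unadjusted p under 0.05 with all times, when 144 h was fitted alone) and in females up to 48 h (1791, 1772, 51, 2496 and 250, with highest others of 1641, 1595, 6, 559 and 143). Without 1 library the count also fell below the highest other split in males at 24 h (136) and in females at 3, 6 and 48 h (976, 978 and 75). In females at 144 h chance cannot be excluded, since 7 of 35 splits gave at least the real count of 159 and the highest other gave 670. Chance can be excluded for the saline sex difference (3037, 1 of 50 splits, highest other 367). For saline 144 h minus 3 h 1 of 35 splits, the real one, gave as many genes (17194, highest other 14199).

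The MHC class II list was lower and the neutrophil list higher from 3 to 48 h, though at 24 h the neutrophil list had adjusted p = 0.0551 with an estimated correlation, and at 12 h only 3 of 7 and 5 of 16 genes were called. Fewer leukocytes of every kind is at odds with the higher neutrophil list from the start, so a test of it adds little. The macrophage and monocyte markers, examined at 24 h only, did not fall as a set (median log2 change 0, quartiles -0.10 and 0.09). Fewer cells that carry MHC class II cannot be told apart. With the lymphocyte score as covariate the effect at 24 h was 88% of that without it (-0.69 ± 0.09 against -0.79 ± 0.07), but the lymphocyte markers had a median of 0.42 CPM, too low to take out what they follow, and fell themselves (median -0.31 at 24 h, Cd19 -1.88). Lower transcription of MHC class II genes in the cells present was not tested.

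G2/M genes were lower at 24 h. With the erythroid score as covariate the effect was 85.1% of that without it (-0.27 ± 0.04 against -0.32 ± 0.04), so the score accounted for little of the effect. Whether the score follows dividing precursors was not tested, so fewer erythroid precursors stays open. A difference in depth was not decided: depth as covariate left 98.6% of the effect (-0.32 against -0.32), but the score is scaled to library size already, so the test moved nothing. No other biological explanation was tested.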
